A study of Rattus norvegicus with 9 samples.

How the data were processed

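Total RNA of uterine tissue was labelled with biotin and hybridised to Affymetrix rat expression arrays, 1 array per sample, in 9 samples of 3 groups. The values analysed were the deposited normalized intensity of each probe set on a linear scale, 1 value per probe set and array. MAS5, Affymetrix's probe summary algorithm, is named in the submitters' processing notes. Its settings, any scaling between arrays and any detection calls are not given in the sources used here. The values alone did not show which summary produced them, so the background level of these intensities is unknown. The deposited intensities ran from 1.87 to 7895.7, with medians of 23.56 to 24.02. Any pair of arrays shared at most 0.44% of exactly equal values, so no array repeated another. The scanner files were not used here.

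The table held 31099 probe sets, of which 57 were Affymetrix controls and were left out. Of the other 31042, the platform annotation gave 1 gene symbol for 20826, several for 436 and none for 9780. Symbols of 20760 probe sets were matched to a RefSeq gene table of the rat, and those without a match kept their symbol. No genome was used, so no coordinates are given. Values were taken as log2(intensity + 16), which understates the change of dim genes, and every log2 fold change is on this scale. Trimmed means (2% from each end) differed by at most 1.086-fold between arrays, under the limit of 1.5, so the deposited normalization was kept. A probe set was kept if it lay at or above the 40th percentile of its own array in at least 3 of the 9 arrays, which left 19326. Among the 14553 of these with 1 symbol, the probe set with the highest mean stood for its gene, which gave 10973 genes.

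Groups followed the condition in the labels, and the 3 comparisons were contrasts of 1 fit to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, 6 residual degrees of freedom, two-sided). Adjusted p-values are Benjamini-Hochberg values within a comparison, and a gene passed at an adjusted p under 0.05. Group values are the mean ± SD of 3 arrays. The 30 gene lists, covering the VEGF system, receptivity, steroid responses, cell types of the uterus and neighbouring tissues, stress, immune and metabolic genes, were tested with camera at a preset correlation of 0.01, adjusted over the lists, with the correlation estimated per list and fry beside it. Lists with under 5 measured members were given no test. The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined.

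In each comparison and direction, the genes named came from the 10 largest in log2 fold change among those that passed, had non-overlapping groups and had a mean above the median gene in the higher group. Symbols that only number a locus were counted and not named. Where under 5 qualified, the genes with the smallest p in that direction filled up to 5 and are said not to pass. Of each list described, up to 4 members with the smallest p were named. Vegfa, Vegfb, Vegfc, Pgf, Flt1, Kdr, Nrp1 and Nrp2 were named in every comparison, and Vegfd and Flt4 were not among the genes tested.

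The fit was tested on simulated arrays with the real genes' means and residual spread, in which 50 genes were changed at each fold size among 10973. With the residual patterns of the measured arrays, 2-fold changes were recovered for 74% of genes in model against control, 68% in treatment against control and 92% in treatment against model. The fold sizes were 1.5, 2, 4 and 8, and calls of the larger ones ease the adjusted threshold for the smaller. Residuals were pooled over the groups and drawn once per comparison, so the shares do not rank the comparisons by power. For the comparisons that share controls, 1000 simulations of unchanged groups gave a correlation and covariance without an effect, with the same spread assumed in all 3 groups. Alternatives were 1 or 64 added before log2, quantile normalization or median centring, no filter or a filter at the 60th percentile, no variance trend or a robust one, array weights, the 6 compared arrays alone, other treatments of multiple probe sets, a replicate block, other thresholds and each array left out in turn. An estimate of array weights gene by gene was added after seeing the data, because the planned estimate did not converge. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.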

Results

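Uterine tissue of female rats was profiled on 9 Affymetrix arrays, 3 from untreated control rats (41, 42 and 43), 3 from model rats (21, 22 and 23) and 3 from treatment rats (31, 32 and 33). Model rats received pregnant mare serum gonadotropin (PMSG, 0.5 U per rat), which drives follicle growth, and 48 h later human chorionic gonadotropin, which triggers ovulation. Treatment rats received the same induction with electroacupuncture at the Guanyuan and Sanyinjiao points, 15 min per session for 7 days before induction and continued during it. The labels describe 18 rats in groups of 6 and do not state that each array came from a separate animal. The p-values therefore measure the spread between these arrays, in the main fit pooled over the 3 groups. No stage of the oestrous cycle was given for the control rats. Median intensities of the 9 arrays were 23.56 to 24.02. After filtering, 10973 genes were tested with limma.

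Control 43 stood apart from the other untreated rats. Its log2 intensities correlated with those of control 41 at r = 0.9446 and of control 42 at r = 0.9594, whereas controls 41 and 42 correlated at 0.9889 across probe sets, which are not independent replicates. The array most similar to control 43 was model 21, at r = 0.985. C3, a complement gene induced by oestrogen in the rat uterus, measured 4.87 on the log2 scale in control 43 and 12.33 and 12.08 in controls 41 and 42. The pooled standard deviation across genes was 0.357 among controls, 0.251 among model arrays and 0.187 among treatment arrays. The first principal component carried 43.1% of the variance and placed control 43 at -24.37, beside model 21 at -24.25, with controls 41 and 42 at 38.28 and 26.66. On the second component, with 27% of the variance, control 43 was the highest of all arrays at 22.82, with controls 41 and 42 at 14.91 and 12.46 and models 21 and 22 at 8.68 and 9.27. The Actb 3' to 5' ratio of control 43, 7.84, was the highest of the 9 arrays (5.07 to 7.84), and its Gapdh ratio of 1.3 lay within the range of 1.1 to 1.39. Control 43 was kept in every main comparison.

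**Figure D1:**
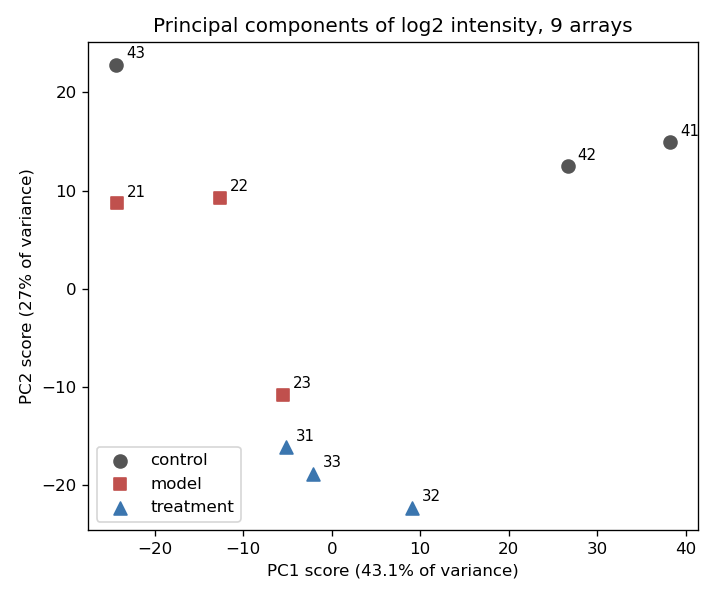
Scores of the 9 arrays on the first 2 principal components of log2 intensity over the tested genes, with the array number beside each point. Controls 41 and 42 lie at 38.28 and 26.66 on the first component, and control 43 at -24.37 lies beside model 21. On the second component control 43 at 22.82 lies beyond every other array.

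The comparison of model with control rats asked what ovulation induction alone changed in the uterus. Igfbp1, which encodes an insulin-like growth factor binding protein made by decidualizing endometrium, rose from 5.21 ± 0.55 to 9.40 ± 0.40 (log2 intensity, SD, n = 3; log2 fold change 4.19, SE 0.39, adjusted p = 0.0355). Sftpd, encoding the collectin surfactant protein D, fell from 7.74 ± 0.19 to 6.11 ± 0.30, a log2 change of -1.64 (SE 0.17, adjusted p = 0.0437). Rnpep, encoding aminopeptidase B, fell from 8.87 ± 0.11 to 7.48 ± 0.30, a log2 change of -1.39 (SE 0.15, adjusted p = 0.0456). These 3 genes, 1 higher and 2 lower, were the calls at an adjusted p under 0.05. Igfbp1, Sftpd and Rnpep each separated the 3 model arrays from the 3 controls, control 43 included. Genes that pass over these same arrays tend to do so, and non-overlapping groups were part of the naming rule. The separation is therefore not separate support. Of the 9 fits that left out an array, Igfbp1 passed in 3, Rnpep in 2 and Sftpd in 1. Igfbp1 in controls 41 and 42 lay near the filter threshold, so the size of its change was uncertain, with log2 fold changes of 3.08 to 4.99 when 64 or 1 was added before log2.

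Genes next in rank did not pass. Cyp26a1, the retinoic acid hydroxylase, measured 7.44 ± 0.73 in model and 4.50 ± 0.07 in control arrays (log2 fold change 2.94, adjusted p = 0.0663). It lay below the filter threshold in all 3 controls, so the size was uncertain, at 1.67 to 4.37 across the settings that left out no single array. Col4a6, a basement membrane collagen chain, differed by 2.01 (adjusted p = 0.0581). Ank3, an ankyrin, and Gaa, the lysosomal acid alpha-glucosidase, differed by 0.69 and 0.57 (adjusted p = 0.107 and 0.119). The glucose transporter gene Slc2a3 (-1.54), Card14 (-1.05) and the palmitoyltransferase gene Zdhhc2 (-0.70) all had an adjusted p of 0.0663. At an unadjusted p under 0.05, 699 genes were higher and 667 lower, 1366 in both directions together, where about 549 would be counted by chance. This excess was not particular to the groups. Model 21, model 22 and control 43 set against the other arrays of the comparison gave 2410. Groups did not overlap for 14.5% of genes, against 10% by chance. The count of genes that passed depended on single arrays: it was 1384 (625 higher, 759 lower) without control 43, 0 without model 21, model 23, control 41 or control 42, and 1 without model 22, treatment 31, treatment 32 or treatment 33. The gene that passed without treatment 32 was not Igfbp1, Sftpd or Rnpep.

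Epithelial markers fell as a group in model against control arrays (camera adjusted p = 5.29e-06, and adjusted p = 0.938 with an estimated correlation). Of 18 measured members 17 had negative log2 fold changes, with a median of -0.72, but 0 passed over all genes and 3 passed adjusted over the list alone: Prom1 (-2.34, adjusted p = 0.162 over all genes), Epcam (-0.68, 0.176) and Cdh1, encoding E-cadherin (-1.19, 0.266). Smooth muscle markers rose as a group (adjusted p = 0.000194, and adjusted p = 0.938 with an estimated correlation), with 17 of 17 members positive and a median of 0.37. Control 41 scored -0.73 for them, against -0.04 and -0.02 in controls 42 and 43 and 0.03 to 0.27 in model arrays, and the adjusted p was 0.0085 without control 41. Lmod1 (0.88, adjusted p = 0.252), Smtn (0.86, 0.266) and Des, encoding desmin (0.72, 0.284), ranked first in that list, in which 0 members passed over all genes and 0 adjusted over the list alone. Epithelial scores per array were 1.27 in control 41, 0.89 in control 42 and -0.43 in control 43, against -0.54 to -0.21 in model arrays. Without control 43, 11 of the 18 epithelial markers passed, all lower, and 2 of the 17 smooth muscle markers, both higher.

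Interferon response genes fell as a group (adjusted p = 0.00774, and adjusted p = 0.938 with an estimated correlation), with 17 of 19 members negative, led by Stat2 (-0.50) and Irf1 (-0.58), both transcription factors of that response. Hypoxia and glycolysis genes fell as a group (adjusted p = 0.00859, and adjusted p = 0.938 with an estimated correlation). Of 21 members in it, 0 passed over all genes and 1 adjusted over the list alone, the glycolytic enzyme gene Pgk1 (-0.67). The interferon call was lost without model 21 (adjusted p = 0.12) or control 41 (0.0958), and the hypoxia call without control 42 (0.14). In the interferon list 0 members passed by either adjustment. Interferon scores were 0.66, 0.34 and -0.21 in controls 41, 42 and 43, against -0.37 to 0.22 in model arrays. Hypoxia and glycolysis scores were 0.13, 0.29 and -0.06 in these controls, against -0.13 to -0.05 in model arrays. In both lists control 43 thus lay within the range of the model arrays. Without control 43, 4 interferon genes passed, all lower, and 6 hypoxia and glycolysis genes, 1 higher and 5 lower. The adipocyte list was higher at an adjusted p of 0.0141, and adjusted p = 0.582 with an estimated correlation, with 0 of 11 members passing over all genes and 2 adjusted over the list alone, Cfd (0.88) and Plin4 (0.65). Without control 43 the adjusted p was 0.114, while the median was 0.65 against 0.41 and 3 of the 11 members passed.

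A further 3 lists were called, each at an adjusted p of 0.938 with an estimated correlation. Cytosolic ribosomal protein genes were higher (adjusted p = 0.0268, median 0.13, 0 of 15 members passing by either adjustment), a call lost without model 22 (0.175), model 23 (0.228), control 42 (0.142) or control 43 (0.055). Steroid receptor and steroid metabolism genes were higher (adjusted p = 0.038), with 0 of 13 members passing over all genes and 1, Cyp26a1, adjusted over the list alone. That call was lost without model 23 (0.11), control 42 (0.073) or control 43 (0.0937). Lymphocyte and natural killer cell markers were higher (adjusted p = 0.038, median 0.44), with 0 of 6 passing over all genes and 2 adjusted over the list alone, Il2rb (0.53) and the perforin gene Prf1 (0.70), a call lost without model 22 (0.21), control 42 (0.14) or control 43 (0.239), or with the last digit of the array number as a replicate block (0.0615). Lymphocyte scores were 0.71 in model 22 and -0.07 and 0.15 in models 21 and 23. No other list passed by camera, the smallest adjusted p being 0.0904 for 16 progesterone-induced genes, of which 2 passed adjusted over the list alone, Cyp26a1 and the glucocorticoid-induced Tsc22d3 (0.80). Without control 43, progesterone-induced (adjusted p = 0.0465) and extracellular matrix genes (0.0449) were also called higher, and oestrogen-induced (0.0465, median -0.56 against -0.14) and heat shock genes (0.0385) lower, each at an adjusted p of 0.853 with an estimated correlation.

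Among 23 receptivity and implantation genes, 1 passed over all genes in model against control, Igfbp1, and 4 adjusted over the list alone, which were Igfbp1, the decidualization transcription factor gene Foxo1 (0.75, adjusted p = 0.199 over all genes), Itgb1 (0.39, 0.266) and Stat3 (-0.34, 0.245). Their median log2 fold change was 0.20, and fry, which asks whether genes of a set change in either direction without comparing them with other genes, gave an adjusted p of 4.96e-06 for the list and 9.86e-07 for the 10 decidual markers. When fry asked for a change in 1 direction these were 0.136 and 0.17. In either direction it also passed for nerve and glial (0.00258), adipocyte (0.00741), steroid (0.0138) and progesterone-induced genes (0.0156). Igfbp1 was a member of the receptivity and the decidual list alike. Decidual markers had a median of 0.016, with 6 members positive and 4 negative. Without control 43, 6 receptivity genes passed over all genes, 3 in each direction, and the receptivity median was 0.06. By camera, receptivity genes did not stand apart (adjusted p = 0.521), nor did decidual markers (0.521). VEGF, a family of vascular growth factors, is named in the study's title. In the VEGF list, which also held Angpt2, Tek, Tie1, Hif1a, Epas1 and Fgf2, 0 of 14 members passed over all genes and 2 adjusted over the list alone. Those were Vegfb at 7.43 ± 0.15 against 6.56 ± 0.44 (log2 fold change 0.87, SE 0.20, adjusted p = 0.199 over all genes) and the co-receptor gene Nrp2 at -0.43 (SE 0.12, adjusted p = 0.266). Vegfa measured 7.24 ± 0.12 in model and 6.97 ± 0.29 in control arrays (0.27, SE 0.14, adjusted p = 0.455). Vegfc differed by 0.15, Pgf by 0.27, Kdr by 0.21, Flt1 by 0.05 and Nrp1 by 0.07, and none of them passed by limma. Leaving out single arrays moved Kdr between 0.016 (control 42) and 0.525 (control 43), Pgf down to 0.018 (model 23) and Vegfc to 0.022 (control 41). Without control 43, Vegfa (0.43, adjusted p = 0.0321), Vegfb (1.02, 0.0189) and Nrp2 (-0.56, 0.0123) passed. Their smallest changes with an array left out were 0.16 for Vegfa and -0.33 for Nrp2 (control 42) and 0.62 for Vegfb (control 41). Flt1 turned to -0.06 without control 42, and Nrp1 to -0.11 without control 42 or control 41 and to -0.12 when its probe sets were averaged.

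The comparison of treatment with control rats asked what induction and electroacupuncture together changed. Igfbp1 rose to 9.18 ± 0.65 from 5.21 ± 0.55 (log2 fold change 3.97, SE 0.39, adjusted p = 0.0162), and Cyp26a1 rose to 8.02 ± 0.61 from 4.50 ± 0.07 (3.52, SE 0.39, adjusted p = 0.0176). Nmb, encoding the peptide neuromedin B, rose from 5.07 ± 0.40 to 7.21 ± 0.24 (2.14, SE 0.27, adjusted p = 0.0311). The retinoic acid-responsive gene Rarres1 fell from 9.78 ± 0.17 to 6.33 ± 0.42, a log2 change of -3.45 (SE 0.46, adjusted p = 0.0311). Sftpd fell to 5.69 ± 0.16 from 7.74 ± 0.19 (-2.05, SE 0.17, adjusted p = 0.0101), and Rnpep to 7.09 ± 0.12 from 8.87 ± 0.11 (-1.78, SE 0.15, adjusted p = 0.0101). Cyp26a1 in all 3 controls lay below the filter threshold of its array, and Igfbp1 and Nmb near it in controls 41 and 42, so the sizes of these changes were uncertain. With 64 or 1 added before log2 they were 2.132 to 5.003 for Cyp26a1, 2.88 to 4.76 for Igfbp1 and 1.26 to 2.88 for Nmb.

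In all, 56 genes passed in treatment against control, 19 higher and 37 lower. Higher genes included Col4a6 (1.66), the scramblase gene Plscr2 (1.49), Gnpda1, a glucosamine-6-phosphate deaminase (1.36), the glutathione transferase gene Gstp1 (1.15), Nt5e, the ectonucleotidase that makes adenosine (1.11), and Pdha1, a pyruvate dehydrogenase subunit (0.82), with adjusted p of 0.0162 to 0.0479. Lower genes included Lratd1 (-3.11), Crip1 (-2.00), Mall (-1.84), Ada, the deaminase that removes adenosine (-1.82), the endothelial transcription factor gene Sox7 (-1.71), Slc2a3 (-1.60) and the aldose reductase gene Akr1b1 (-1.59), with adjusted p of 0.0176 to 0.0428. A second, dimmer probe set of Akr1b1 gave 0.07. At an unadjusted p under 0.05, 718 genes were higher and 1187 lower, and 23.3% of genes had non-overlapping groups, against 10% by chance. Under quantile normalization the calls split into 27 higher and 28 lower, and the surplus at an unadjusted p under 0.05 turned around, to 1057 higher and 735 lower. With the 6 compared arrays alone, 52 genes passed, 27 higher and 25 lower, and only 26 of them were among the 56. The count was 720 (163 higher, 557 lower) without control 43 and 95 without model 23. It was 13 without model 22, 11 without treatment 32, 5 without control 42, 4 without control 41, 2 without treatment 31 and 0 without treatment 33. Sftpd kept an adjusted p under 0.05 in 8 of the 9 fits that left out an array, Rnpep in 7, Igfbp1 in 6 and Cyp26a1 in 5. The other genes named for this comparison did so in 1 (Mall) to 4 (Akr1b1, Gnpda1 and Rarres1) of these fits.

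**Figure D2:**
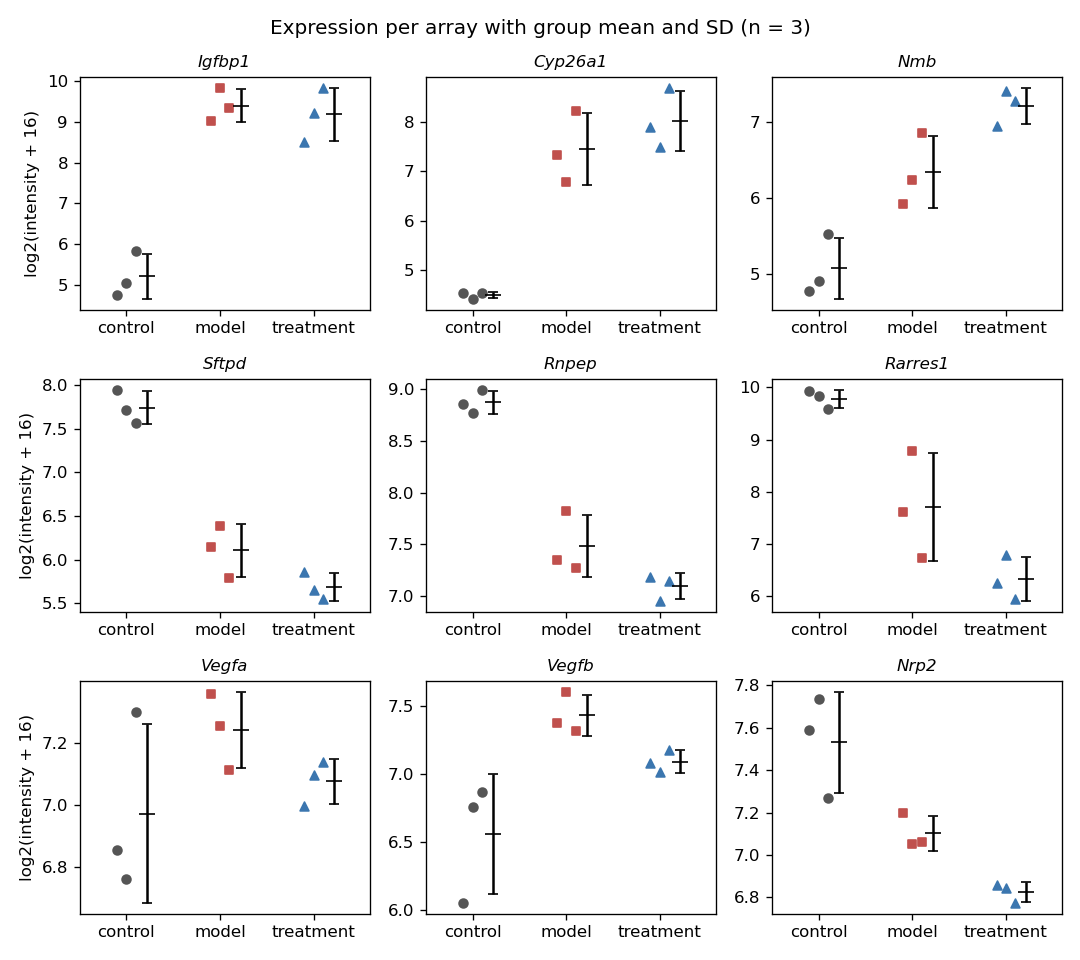
Log2(intensity + 16) of 9 genes in each array, with the mean and SD of each group (n = 3) drawn to the right of its points. Cyp26a1 lies at 4.42 to 4.54 in all 3 controls and at 6.78 to 8.68 in the other 6 arrays, whereas the control arrays of Vegfa and Vegfb spread widely.

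Smooth muscle markers rose as a group in treatment against control arrays (adjusted p = 2.37e-05, and adjusted p = 0.931 with an estimated correlation), with 16 of 17 members positive, a median of 0.33 and 0 passing over all genes or adjusted over the list alone. Des (0.83, adjusted p = 0.128), Smtn (0.68, 0.222) and Actg2, a smooth muscle actin gene (0.56, 0.246), ranked first. Treatment 33 scored -0.05 for these markers, no higher than controls 42 and 43, and without control 41 the adjusted p was 0.0379. Epithelial markers fell as a group (adjusted p = 0.0217, and adjusted p = 0.931 with an estimated correlation), with 16 of 18 negative, 0 passing over all genes and 1, Prom1 (-2.55, adjusted p = 0.0625 over all genes), adjusted over the list alone. Interferon response genes fell as a group (adjusted p = 0.0217, and adjusted p = 0.931 with an estimated correlation), with 16 of 19 negative, 0 passing by either adjustment and Stat2 (-0.58) and Ifit2 (-0.76) first in rank. The epithelial call was lost without treatment 31 (adjusted p = 0.0714), control 41 (0.288) or control 42 (0.111). The interferon call was lost without treatment 33 (0.23), control 41 (0.271) or control 42 (0.111). Control 43 scored -0.43 for epithelial markers and -0.21 for interferon genes. Treatment arrays scored -0.47 to -0.01 and -0.40 to 0.13, so control 43 lay within their range in both lists. Without control 43 the adjusted p was 6e-07 for epithelial markers, with 5 of 18 passing, and 0.000108 for interferon genes, with 6 of 19 passing, all lower. Heat shock (0.0123) and hypoxia genes (0.0482) were then also called lower, and all 4 lists had an adjusted p of 0.884 with an estimated correlation. The smallest adjusted p among the other lists was 0.144, for oxidative phosphorylation genes (19 of 27 positive, 0 passing by either adjustment).

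**Figure D3:**
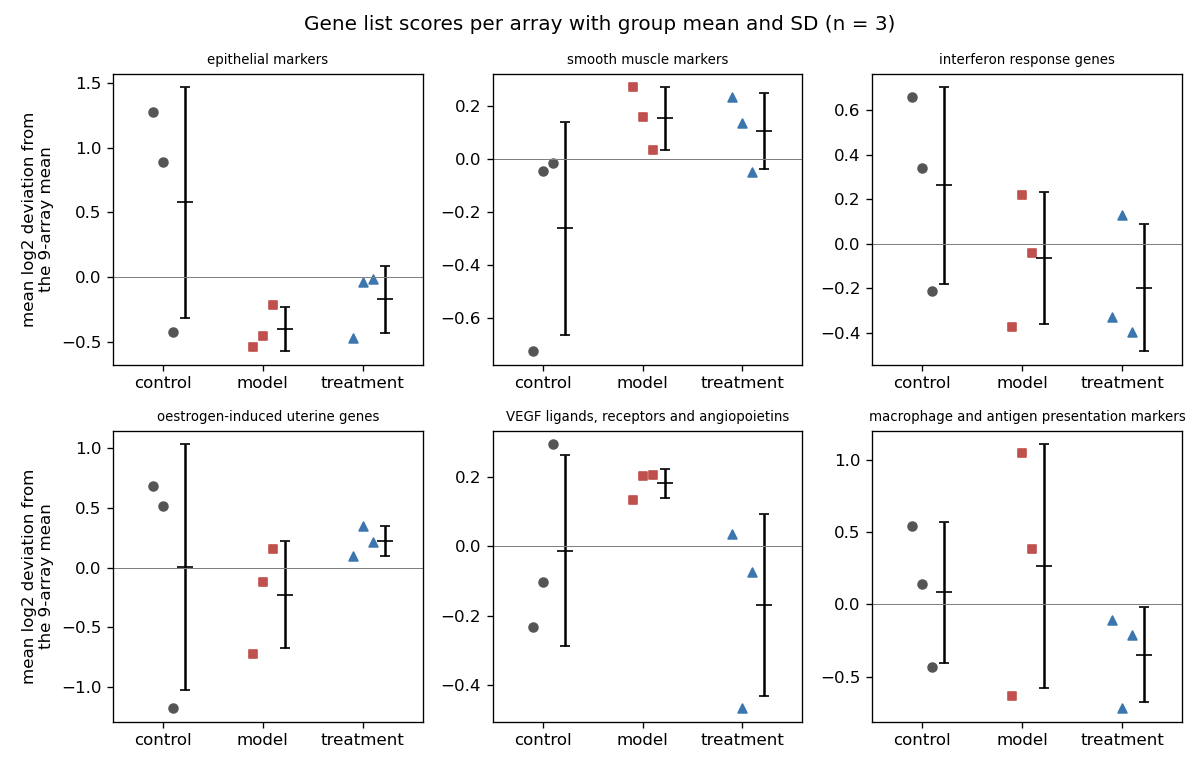
Score of 6 gene lists in each array, as the mean log2 deviation of their measured genes from the 9-array mean, with the mean and SD of each group (n = 3). Control 43 scores -0.43 for epithelial markers and -1.18 for oestrogen-induced genes, where controls 41 and 42 score 1.27 and 0.89, and 0.69 and 0.52.

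Among receptivity and implantation genes, 1 of 23 passed over all genes in treatment against control, Igfbp1, and 6 adjusted over the list alone, among them Stat3 (-0.45, adjusted p = 0.0663 over all genes), Spp1, encoding osteopontin (3.96, 0.118), and Sgk1, a steroid-induced kinase gene (1.22, 0.124). The list's median was -0.17, its mean 0.20, and camera gave an adjusted p of 0.701. Without control 43 the median was -0.04 and 5 members passed, 2 higher and 3 lower. By fry in either direction, 10 lists passed, among them receptivity genes and decidual markers (both 5.07e-06) and the VEGF list (0.0161), and in 1 direction these gave 0.911, 0.626 and 0.911. Igfbp1 was a member of the receptivity and decidual lists alike, and the decidual median was -0.008, with 5 members of each sign. Of 13 steroid receptor and metabolism genes, Cyp26a1 passed over all genes, and Cyp26a1 and Hsd11b1, which regenerates active glucocorticoid (3.38, adjusted p = 0.126 over all genes), adjusted over the list alone. The camera test of that list gave an adjusted p of 0.199. Of the VEGF list, 0 of 14 members passed over all genes and 1 adjusted over the list alone, Nrp2, at 6.83 ± 0.05 against 7.53 ± 0.24 (-0.71, SE 0.12, adjusted p = 0.0568 over all genes). Nrp1 differed by -0.84 (SE 0.31, adjusted p = 0.238) and Vegfb by 0.53 (SE 0.20, adjusted p = 0.241). Vegfa measured 7.08 ± 0.07 against 6.97 ± 0.29 (0.11, SE 0.14, adjusted p = 0.744), with -0.001 without control 42 and 0.27 without control 43. Vegfc differed by -0.31, Pgf by 0.18, Kdr by -0.28 and Flt1 by -0.01, and none passed by limma. Nrp1 was -0.49 without control 43, Vegfb 0.28 without control 41, Vegfc -0.16 without treatment 32 and Pgf 0.07 without treatment 31. Without control 43, Nrp2 passed (-0.84, adjusted p = 0.00358), and Kdr and Flt1 turned to 0.04 and 0.15.

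The comparison of treatment with model rats set electroacupuncture with induction against induction alone. With limma, 0 genes passed, and the smallest adjusted p was 0.286. The spread in this fit was pooled over all 3 groups and so included that of the controls, the largest of the 3. With the 6 compared arrays alone the smallest limma adjusted p was 0.182, and without control 43 it was 0.125, again with 0 genes passing. Genes with the smallest p in the higher direction were the glycolytic regulator Pfkfb3 at 5.95 ± 0.02 against 5.57 ± 0.05 (log2 fold change 0.38, SE 0.07), the histone mRNA binding protein gene Slbp (0.58), Tm6sf2 (0.58), the amino acid transporter gene Slc7a5 (0.42) and Krt71 (0.36). In the lower direction they were Cped1 at 6.69 ± 0.22 against 7.97 ± 0.32 (-1.27), Adap2 (-0.74), the phospholipase gene Plcg1 (-0.70), Ddit3, a transcription factor of the unfolded protein response (-0.68), and Vgll4 (-0.50). These 10 genes shared the adjusted p of 0.286. Tm6sf2 lay below the filter threshold in all 3 model arrays. Pfkfb3, Slc7a5 and Krt71 were dim too, so the sizes of these changes were uncertain. Across the settings that left out no single array, they ran from 0.222 to 1.184 for Tm6sf2 and 0.081 to 0.533 for Pfkfb3. For Slc7a5 they ran from 0.204 to 0.623, and for Krt71 from 0.179 to 0.53. Of Pfkfb3, a second, dimmer probe set gave -0.22.

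At an unadjusted p under 0.05, 501 genes were higher and 1110 lower in treatment than in model arrays, and 28% of genes had non-overlapping groups, against 10% by chance. Under quantile normalization these were 768 higher and 609 lower, again with 0 genes passing. The trimmed mean intensities of the treatment arrays, 59.82, 60.54 and 62.07, were below those of the model arrays, 62.97, 64.97 and 64.88. Every other planned setting with all 3 model arrays also gave 0 genes, and 3 genes, all higher, passed without model 23. On simulated arrays with the measured residual patterns, 92% of 2-fold and 62% of 1.5-fold changes were recovered in this comparison, with 8 false calls. With independent noise these shares were 78% and 56%. Changes of 4- and 8-fold were simulated beside them, and such calls ease the adjusted threshold for smaller changes. The shares therefore do not give the power of a comparison in which 0 genes passed. Cped1, at 2.42-fold, had an adjusted p of 0.286 by limma.

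Vegfa measured 7.08 ± 0.07 in treatment and 7.24 ± 0.12 in model arrays (log2 fold change -0.17, SE 0.14, adjusted p = 0.583), and Vegfb 7.09 ± 0.08 and 7.43 ± 0.15 (-0.34, adjusted p = 0.44). Nrp1 differed by -0.91 (SE 0.31, adjusted p = 0.286), Vegfc by -0.46 (0.307), Nrp2 by -0.28 (0.343) and Kdr, the main VEGF receptor of endothelium, by -0.48 (0.496). Pgf and Flt1 differed by -0.09 and -0.05. Without treatment 32, Kdr was -0.17 and Vegfc -0.31, and Vegfa was -0.11 without model 21. Pgf turned to 0.165 without model 23 and Flt1 to 0.041 without treatment 32. Of the 14 VEGF list members 13 were negative, 0 passed over all genes or adjusted over the list alone, and camera gave an adjusted p of 0.173. The list passed under quantile normalization (adjusted p = 0.0327) and without treatment 31 (0.0143), against an adjusted p of 0.512 without treatment 32 and of 0.78 with an estimated correlation. VEGF scores per array were 0.04, -0.47 and -0.08 in treatments 31, 32 and 33 and 0.13 to 0.21 in model arrays. Endothelial markers gave an adjusted p of 0.171, with 13 of 14 negative, 0 passing over all genes and 1 adjusted over the list alone, the von Willebrand factor gene Vwf (-0.76). Treatment 32 stood apart in that list at -0.75, against 0.04 and -0.02 in treatments 31 and 33.

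Of the remaining lists in treatment against model, macrophage and antigen presentation markers had 18 of 20 members negative with a median of -0.71 (adjusted p = 0.171, and 0 members passing by either adjustment). Their scores ranged from -0.63 in model 21 to 1.05 in model 22, and from -0.72 to -0.11 in treatment arrays. Fibroblast markers had 15 of 16 negative with a median of -0.37 (adjusted p = 0.173), led by the growth factor receptor gene Pdgfra (-1.04), and scored -0.57 in treatment 32 against -0.01 and -0.03 in treatments 31 and 33. Adipocyte markers had 10 of 11 negative (adjusted p = 0.225), with 1 member, Cfd (-0.74), passing adjusted over the list alone. Adjusted over their lists alone, Ddit3, Pfkfb3, the ceruloplasmin gene Cp (-1.65) and the nitric oxide synthase gene Nos2 (0.46) also passed. No list passed in this comparison, and oestrogen-induced genes, with a median of 0.18, gave an adjusted p of 0.202.

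The 2 comparisons against control shared their 3 control arrays. Across genes, which are not independent replicates, their log2 fold changes correlated at r = 0.677 with a covariance of 0.0807, and 64.5% had the same sign. Unchanged groups simulated against shared controls gave a median r of 0.572 (-0.511 to 0.963), a mean covariance of 0.0261 (-0.0177 to 0.1159) and 68.6% of the same sign. The observed correlation and covariance lay within the simulated ranges, and the share of the same sign lay below the simulated value. Every simulated group was drawn from residuals pooled over the 3 groups. The measured controls spread more, with a pooled SD of 0.357 against 0.251 in model and 0.187 in treatment arrays. The simulated median r and mean covariance therefore probably understate what shared controls alone give, and the observed values are no evidence of agreement beyond that. The single gene called higher in model, Igfbp1, was also among the 19 higher in treatment, where independent lists would share 0.0017, and both lower genes, Sftpd and Rnpep, were among the 37 lower, where 0.0067 would be shared. These values for independent lists leave out the shared controls, and part of the overlap may come from the controls, which are too few to split.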

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

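Array weights by the gene-by-gene method were an alternative chosen after seeing the data, and the other settings were planned. Lists not called with all 9 arrays, the VEGF list aside, were examined without control 43 only and not without any other array. In model against control, where 3 genes passed, the count was 1 with no filter on low values, 1 with the 6 compared arrays alone, 5 with every probe set on its own and 9 at an adjusted p under 0.1. The gene that passed with the 6 compared arrays alone was none of the 3. The planned array weights gave 3149, with an estimate that did not converge and a weight of 13.539 for control 42 against 0.2 for control 43, and the gene-by-gene weights gave 852. Leaving out each array gave 0 (lowest without model 21, model 23, control 41 or control 42) to 1384 (without control 43). In treatment against control, with 56 genes, the array weights gave 3552 and 1277, an adjusted p under 0.1 gave 164 and the 2-fold minimum 27. Leaving out each array gave 0 (without treatment 33) to 720 (without control 43). In treatment against model the count was 0 except without model 23, where it was 3. Calls lost through smaller sets of arrays include the effect of fewer residual degrees of freedom, which does not account for calls gained. The large gains without control 43 came with the removal of the array furthest from its group mean. Its root mean square deviation over genes was 0.383, against 0.131 to 0.267 in the other arrays. Other causes were not tested. The last digit of the array number, taken as a replicate block, gave 27 genes in treatment against control, 19 of them shared with the 56. It gave 4 in model against control, 2 of them shared with the 3, and 0 in treatment against model. Deviations of same-digit arrays correlated at -0.408 to 0.311, and 2 of 9 arrays correlated best with their own digit. With 3 arrays per group, this check is too weak to exclude that arrays of the same digit were handled together. Of single genes, Nrp1 turned to -0.12 in model against control with the mean of its probe sets (-0.11 to 0.41 with arrays left out). Flt1 ranged from -0.059 to 0.20 with arrays left out and from 0.017 to 0.265 in the other settings. In those it passed in 1 of 13 (limma adjusted p = 0.0453), and Vegfa, Vegfb and Nrp2 each passed in 2 of 14. In treatment against control, Flt1 turned to 0.001 with 1 added and to 0.23 and 0.18 under the 2 array weights (-0.11 to 0.15 with arrays left out), and Kdr to 0.20 and 0.11 (-0.51 to 0.043). Vegfa ranged from -0.001 to 0.27 with arrays left out and from 0.073 to 0.293 in the other settings. In those it passed in 1 of 14 (limma adjusted p = 0.0198), as did Vegfb (0.046) and Vegfc (0.0369), and Nrp2 passed in 2. In treatment against model, Pgf turned to 0.046 with the mean of its probe sets (-0.22 to 0.17) and Flt1 ranged from -0.11 to 0.041. The VEGF list in treatment against control had an adjusted p of 0.424 to 0.884 and turned upward without treatment 32 (0.709) or control 43 (0.657). The correlation of the 2 comparisons against control stayed at 0.679 with no filter and 0.678 under quantile normalization. No detection calls were used, so signal over background is unknown.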

Other observations

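The tests on control 43 were chosen after its values were seen, and the gene lists used in them were fixed before. Several extracellular matrix and transport genes had large differences that did not pass over all genes. Mmp7, a matrix metalloproteinase of uterine epithelium, measured 6.42 ± 1.92 in treatment and 11.13 ± 1.42 in control arrays (SD, n = 3; log2 fold change -4.71, limma adjusted p = 0.0962), and Bgn, encoding biglycan, differed by 0.89 (0.141). In model against control, Bgn differed by 1.05 (adjusted p = 0.203) and Timp2, a metalloproteinase inhibitor gene, by 0.65 (0.208). The sodium pump subunit gene Atp1b1 differed by 1.03 in treatment against control (adjusted p = 0.106), and Slc34a2, a phosphate transporter gene, by 1.81 (0.132). Slc34a2 differed by 1.83 and the water channel gene Aqp8 by 1.99 in treatment against model (adjusted p = 0.286 and 0.354). Camera gave adjusted p of 0.124 and 0.95 for the matrix list against control in model and treatment arrays, and 0.86 and 0.2 for the transport list.

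Control 43 differed from the other untreated rats over many genes: 308 were over 2-fold lower and 196 over 2-fold higher in it than in both, while 93 lay over 2-fold apart between controls 41 and 42. Beside C3, the epithelial keratin gene Krt19 (7.48 against 12.01 and 11.58) and Lcn2, encoding lipocalin 2 (4.65 against 9.82 and 9.17), were lower, and Calca, encoding calcitonin and its related peptide (9.07 against 5.70 and 5.34), was higher. Macrophage markers were lower than in both for 19 of 20 members. Endothelial markers had a median difference of 0.58, fibroblast markers of 0.76 and VEGF list members of 0.48. These genes were chosen after their values were seen.

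Fewer epithelial cells as the whole cause of the position of control 43 is argued against by 5 of 18 epithelial markers that rose or fell by under 0.5 while their median was -1.12. A lower oestrogen response than in controls 41 and 42 stays open: the median of 17 oestrogen-induced genes was -1.56, at percentile 0 of 10000 random lists matched on expression, but epithelial, epithelial defence, macrophage, interferon and heat shock lists also lay at percentile 0, and Igf1 (1.93), Aqp5 (1.46) and Myc (0.70) were higher in control 43. A wrong label stays open too, because control 43 lay on the control side at 6.7% of 905 genes separating controls 41 and 42 from the stimulated arrays, within the 0.3 to 10.4% of the stimulated arrays left out in turn, although 5 of those 6 lay lower. A second test, added after that result, took the 50 genes with the smallest p and found 1 on the control side in control 43, against 0 to 2 in the left-out arrays. Calca (9.07) was at 5.17 to 5.62 in the stimulated arrays, and the 61 genes on the control side included Igfbp1 (5.83 in control 43, 9.29 on average in stimulated arrays) and Cyp26a1 (4.54 and 7.73), but these genes were picked by their values in control 43 and do not weigh against a wrong label.

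The surplus of genes lower in treatment than in model arrays, 68.9% of those at an unadjusted p under 0.05, may come from array scaling, since the share was 44.2% under quantile normalization, although 70.2% under median centring. It was 52.6% with no filter on low values and 80.8% with the filter at the 60th percentile. A single model array with high macrophage markers as the cause is argued against by a share of 70.5% without model 22. An effect of electroacupuncture on these genes stays open and was not tested apart from the comparison itself.

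Each comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05. In model against control the real split gave 3 genes and the highest other 79, and 3 of 10 splits gave as many. The split with 79 set model 21, model 22 and control 43 against model 23, control 41 and control 42, many more than the real one, which points to a structure of the arrays other than the groups. In treatment against control the real split gave 56 genes and the highest other 5, with 1 of 10 as large, and in treatment against model all 10 gave 0. At an unadjusted p under 0.05, the real split gave 1366 genes in model against control and the highest other 2410. These counts were 1905 and 1772 in treatment against control, and 1611 and 729 in treatment against model.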
